A study of Mus musculus with 18 samples.

How the data were processed

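RNA of 18 mouse samples was hybridized to single-dye microarrays. Per the labels, RNA was extracted with Trizol and RNeasy columns and labelled with a cyanine dye. The authors deposited linear probe intensity values, background-subtracted as the values below 0 show (743 to 1042 probes per array, minimum -9); the scanner software and any normalization before deposit are not given in the sources used here. The highest values per array lay between 65465 and 65478, and 1 to 4 probes exceeded 65000. No pair of arrays held identical values.

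Probes were named from the platform annotation: 21876 of 26423 probes had 1 gene symbol, 0 had several and 4547 had none, for 19084 genes, of which 2424 had several probes. Gene identifiers of 21825 probes were in the RefSeq gene table used, with 0 differing symbols. Where a gene had several probes, the probe with the highest mean over all 18 arrays stood for it. No genome sequence was used. Gene positions in the RefSeq table (GRCm38.p6) served only to find the genes nearest to Cebpa, among those above background in an untreated group.

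Median and mean intensities differed between arrays, so intensities were quantile normalized over the arrays of each fit and transformed as log2(intensity + 16). Fold changes are on this scale, which understates the change of dim genes. Intensities beside a fold are means of normalized intensities over 3 arrays with their SD. A probe under an intensity of 30 on every array of a group, a limit chosen after the data were seen, was treated as at background there. Its fold is given as at least the ratio of the brighter group's mean to the dim group's values, each raised to that limit. A difference of drug effects is given as such a bound where a group at background could only widen it.

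Comparisons were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over 26423 probes and a threshold of 0.05. Basophils and mast cells were fitted on their 6 arrays. The 12 arrays of cultured basophils shared a fit with a mean per group, from which came floxed against wild type with and without the drug, the drug effect in each genotype, and the interaction. These designs, the gene lists, the naming rule and most alternatives were fixed before the data were examined. Named genes were the 10 highest and 10 lowest log2 fold changes in basophils against mast cells and in treated floxed against treated wild type cells, and the 5 highest and 5 lowest elsewhere. They were taken among genes past the test whose replicates did not overlap between groups, with no overlap rule for the interaction; Cebpa and Mitf were named in every comparison. Up to 4 members of a list were named, by the size of their change among those that passed; some list members in the text beyond these were chosen after their values were seen.

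The 23 gene lists held 371 genes, some in several lists, and covered basophil markers, mast cell markers, granule proteases, Fc epsilon receptor signalling and exocytosis, haematopoietic transcription factors, cytokines and chemokines, cytokine and chemokine receptors, histamine and eicosanoid pathway, neutrophil granule and maturation genes, eosinophil markers, monocyte and macrophage markers, B cell markers, T and NK cell markers, erythroid markers, megakaryocyte and platelet markers, stem and progenitor markers, cell cycle, p53 targets, cholesterol biosynthesis, interferon-stimulated genes, MHC class II and costimulation, immediate early and handling genes and housekeeping genes. Camera tested each list with a preset correlation of 0.01, and with an estimated correlation and fry as alternatives, with Benjamini-Hochberg adjustment over the lists of a comparison. Counts adjusted over the list alone used the list's members as the only tests. Genes at least 2-fold different between basophils and mast cells formed a set for each direction, tested in the other comparisons with camera.

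Alternatives were median scaling, a filter on the dimmest 30% of probes, an offset of 50, an intensity trend, no variance moderation, array weights, all 18 arrays in a fit, only the groups compared, the replicate number as a block, probes averaged per gene, a 2-fold threshold and each array left out in turn. Added after seeing the data were no between-array normalization, scaling on probes above background, only probes above background and leaving out probes that switched between background and bright within a group. The scripts were tested on simulated data with known changes in 26423 probes. For basophils against mast cells, 23.9%, 71.6% and 95.5% of probes changed by 0.5, 1 and 2 log2 units were recovered, with 5 false calls. For treated floxed against wild type cells the shares were 55.2%, 91.0% and 97.0% (6 false calls), and for the interaction 7.46%, 76.1% and 97.0% (3 false calls).

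Within groups, the median SD of a probe over an intensity of 100 was 0.0798 to 0.105 log2 units, and pairs of arrays had Pearson's r across probes of 0.990 to 0.993. Scaling moved the median of all probes by over 0.1 log2 units in 5 of the comparisons. Without normalization, with median scaling and with scaling on probes above background the move was 0.20, -0.12, -0.32 for basophils against mast cells and 0.12, -0.17, -0.081 for the interaction. In the same order it was 0.031, -0.076, -0.11 for treated floxed against wild type cells, -0.076, 0.12, -0.010 for untreated ones, and -0.090, 0.12, 0.042 for the drug in the wild type.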

Results

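Gene expression was measured with single-dye microarrays of 26423 probes in 18 samples from C57Bl/6 mice, which fell into 6 groups of 3 arrays. Basophils, rare granulocytes of allergic and antiparasite responses, were purified from bone marrow 3 days after mice had received a complex of interleukin-3 and its antibody. Mast cells, tissue cells that share granule mediators and the IgE receptor with basophils, had been grown from bone marrow for 4 weeks with 20 ng/ml interleukin-3. The other 4 groups were basophils kept for 5 days in 20 ng/ml interleukin-3, from mice with normal or loxP-flanked (floxed) Cebpa that carried a tamoxifen-inducible Cre recombinase and a fluorescent reporter. Each genotype was cultured with 100 nM 4-hydroxytamoxifen, which activates the recombinase, or without it. The study asked which genes set basophils apart from mast cells and which genes depend on Cebpa, a transcription factor of myeloid cells, in basophils.

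Median probe intensity was 24 to 42 per array, mean intensity 461 to 700.1, and 47.3% to 54.8% of probes lay above an intensity of 30. The number of arrays limits the precision. The labels do not say whether replicates came from separate mice or cultures, so p-values measure only the spread between these samples, which may be technical. Values in brackets after a gene are log2 fold changes ± SE with n = 3 arrays a group, or a lower bound of the fold where one group lay at background. Gene lists are given as members higher and lower past the test over all probes, the median log2 fold change, and camera's adjusted p.

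Cebpa, the targeted gene, was read at normalized intensities of 2232, 2393 and 2105 on the 3 arrays of purified basophils and 56.8, 63.8 and 45.7 on those of mast cells. Wild type cultured basophils gave 2280.2, 2602 and 2226 without the drug and 2973, 2822 and 2539 with it. Floxed basophils gave 1055, 935 and 959 without the drug and 69.1, 69.4 and 57.8 with it, so that all 3 treated floxed arrays lay below all wild type arrays. Whether the probe lies in the deleted part is not given in the sources used here.

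**Figure D1:**
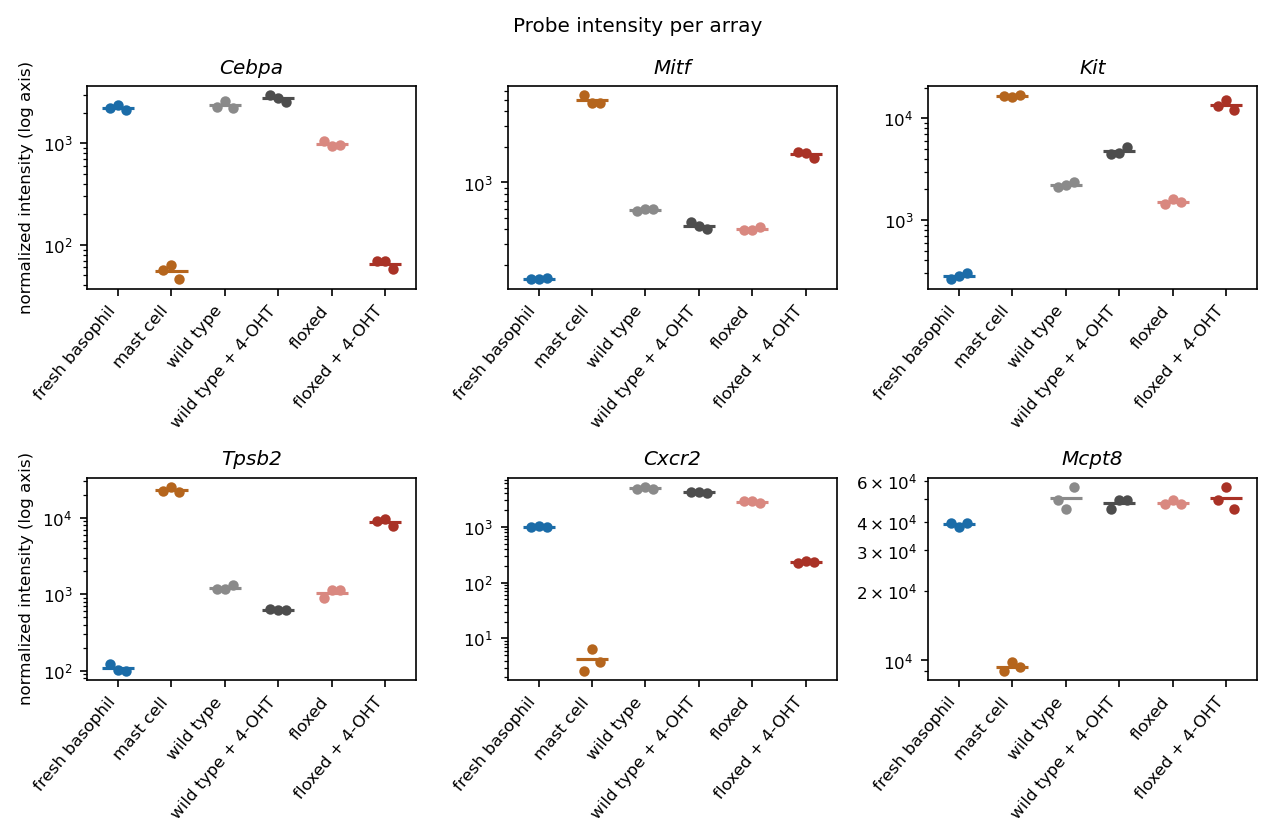
Normalized intensity (log axis) of 6 genes on each of the 18 arrays; points are arrays and lines are group means. Cebpa lay between 57.8 and 69.4 in floxed basophils with the drug, while Mitf, Kit and Tpsb2 were higher there than in the other cultured basophils and Cxcr2 was lower.

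Purified basophils were compared with mast cells to find the genes that differ between them. The basophils came fresh from mice and the mast cells from 4 weeks of culture, so cell type coincided with culture. Cebpa was 33.2-fold higher in basophils (5.05 ± 0.12, adjusted p = 2.19e-08), with an intensity of 2369.7 ± 142 (SD, n = 3) against 56.2 ± 9.24. Mitf, a transcription factor of mast cells and melanocytes, was 30.3-fold higher in mast cells (-4.92 ± 0.10, adjusted p = 1.11e-08). The genes most raised in basophils included the immediate early factor Fos (at least 605-fold higher), the resistin-like gene Retnlg (at least 437-fold), the antimicrobial peptide Camp (8.41 ± 0.18), the iron exporter Slc40a1 (8.37 ± 0.25) and the adhesion molecule Vcam1 (8.33 ± 0.16). The genes most raised in mast cells included the chymase Mcpt2 (at least 689-fold higher there), Tph1, the first enzyme of serotonin synthesis (at least 569-fold), Rprm (-8.55 ± 0.092), the chymase Cma1 (-8.04 ± 0.10) and the tryptase Tpsb2 (-7.53 ± 0.11).

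The remaining genes at the top of the ranking in basophils were Rnase12 (at least 256-fold), the kinase phosphatase Dusp1 (at least 269-fold), Ifitm6 (at least 179-fold), the complement component C1qa (at least 317-fold) and Syndig1 (7.91 ± 0.11). In mast cells they were the actin nucleator Cobl (at least 134-fold), the receptor Cd96 (-7.43 ± 0.12), the heparan sulfate sulfotransferase Hs6st2 (at least 122-fold), Ahrr (-6.59 ± 0.10) and the prion protein gene Prnp (-6.57 ± 0.10). Adjusted p over these 20 genes was 7.02e-08 at most. In all, 9988 of 26423 probes passed the test, 4518 higher and 5470 lower in basophils, and 3449 of them differed at least 2-fold (1877 higher and 1572 lower).

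Basophil markers were higher in basophils, led by Ccl3 (6.33 ± 0.12), Il4 (at least 38.7-fold higher), Ccl4 (5.94 ± 0.10) and Prss34 (4.77 ± 0.095). The median of 14 members was 2.80 (2.44 with members at background set to their bound), with 10 higher and 2 lower (12 adjusted over the list alone) and adjusted p = 3.96e-06. Ifitm1 (-2.28 ± 0.11) and Hgf (at least 1.14-fold lower) of that list were lower. Mast cell markers were lower in basophils, led by Mcpt2 (at least 689-fold lower), Tph1 (at least 569-fold lower), Cma1 (-8.04 ± 0.10) and Tpsb2 (-7.53 ± 0.11). In this list 2 of 18 members were higher and 12 lower (15 adjusted over the list alone), at a median of -1.86 and adjusted p = 1.03e-05. Granule proteases went both ways, with the largest changes in Mcpt2 (at least 689-fold lower), Cma1 (-8.04 ± 0.10), Tpsb2 (-7.53 ± 0.11) and Tpsg1 (-6.20 ± 0.13). Of 14 members, 4 were higher and 7 lower (11 adjusted over the list alone), with a median of -0.36 and adjusted p = 0.226. The basophil proteases Mcpt8 (1.94 ± 0.091) and Prss34 (4.77 ± 0.095) were higher in basophils.

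Markers of other marrow cells, whose admixture was not tested, were higher in basophils too. Neutrophil granule and maturation genes were higher, led by Camp (8.41 ± 0.18), S100a9 (7.41 ± 0.10), Mpo (7.31 ± 0.10) and Lcn2 (5.89 ± 0.11). The median of 17 members was 4.39, with 16 higher and 0 lower (16 adjusted over the list alone) and adjusted p = 1.80e-15. Eosinophil markers were higher, with the largest changes in Prg2 (7.61 ± 0.12), Alox15 (at least 90.6-fold higher) and Prg3 (at least 56.0-fold higher). In this list 6 of 7 members were higher and 1 lower (7 adjusted over the list alone), at a median of 5.39 and adjusted p = 3.47e-05. Monocyte and macrophage markers were higher, led by C1qa (at least 317-fold higher), C1qb (at least 41.9-fold higher) and Mrc1 (at least 56.4-fold higher). Of 14 members, 12 were higher and 2 lower (14 adjusted over the list alone), with a median of 3.41 (3.14 with members at background set to their bound) and adjusted p = 5.18e-07. Erythroid markers were higher, led by Slc4a1 (at least 5.57-fold higher) and Alas2 (at least 8.16-fold higher). The median of 8 members was 1.39 (0.85 with members at background set to their bound), with 7 higher and 0 lower (7 adjusted over the list alone) and adjusted p = 2.91e-05.

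Immediate early and handling genes, which respond within minutes to stimulation or cell isolation, were higher in basophils, led by Fos (at least 605-fold higher), Dusp1 (at least 269-fold higher) and Egr1 (7.77 ± 0.12). In this list 14 of 16 members were higher and 0 lower (14 adjusted over the list alone), at a median of 4.63 (4.56 with members at background set to their bound) and adjusted p = 2.31e-12. Cell cycle genes were higher, led by Kif11 (1.84 ± 0.093), Bub1b (1.69 ± 0.14) and Tpx2 (1.66 ± 0.11). Of 24 members, 23 were higher and 0 lower (23 adjusted over the list alone), with a median of 0.95 and adjusted p = 1.28e-10. Interferon-stimulated genes were higher, led by Irf7 (4.13 ± 0.12), Cxcl10 (at least 12.6-fold higher) and Ifit2 (3.35 ± 0.094). The median of 14 members was 2.31 (1.97 with members at background set to their bound), with 11 higher and 1 lower (12 adjusted over the list alone) and adjusted p = 6.25e-07. The shifts of these lists and of the markers of basophils, mast cells, neutrophils, eosinophils, macrophages and red cells also passed with an estimated correlation, 9 lists in all.

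Other lists passed with the preset correlation alone. Cytokines and chemokines were higher in basophils, with the largest changes in Cxcl2 (at least 103-fold higher), Ccl3 (6.33 ± 0.12) and Il4 (at least 38.7-fold higher). In this list 14 of 24 members were higher and 5 lower (19 adjusted over the list alone), at a median of 0.58 and adjusted p = 6.88e-04 (adjusted p = 0.0686 with an estimated correlation). Cytokine and chemokine receptors were higher, with the largest changes in Kit (-5.78 ± 0.10), Cxcr2 (at least 36.1-fold higher) and Il4ra (-5.75 ± 0.10). Of 25 members, 16 were higher and 9 lower (25 adjusted over the list alone), with a median of 1.13 and adjusted p = 0.0215 (adjusted p = 0.0833 with an estimated correlation). The call was lost without between-array normalization (adjusted p = 0.456), and over all settings adjusted p was 1.69e-06 to 0.456. MHC class II and costimulation genes were higher, with the largest changes in Cd86 (at least 16.2-fold higher) and Cd74 (3.02 ± 0.13). The median of 11 members was 0.85 (0.72 with members at background set to their bound), with 7 higher and 2 lower (10 adjusted over the list alone) and adjusted p = 0.00657 (adjusted p = 0.0780 with an estimated correlation). Megakaryocyte and platelet markers were higher, with the largest changes in Vwf (-3.27 ± 0.10) and Pf4 (3.05 ± 0.14). In this list 6 of 8 members were higher and 1 lower (8 adjusted over the list alone), at a median of 1.36 (0.97 with members at background set to their bound) and adjusted p = 0.00341 (adjusted p = 0.0833 with an estimated correlation). It did not pass without between-array normalization (adjusted p = 0.0515), and over all settings adjusted p was 9.18e-05 to 0.0833. Cholesterol biosynthesis genes were lower, led by Sqle (-1.33 ± 0.10) and Msmo1 (-1.17 ± 0.10), though the median was 0.045 without between-array normalization. Of 17 members, 1 was higher and 10 lower (13 adjusted over the list alone), with a median of -0.42 and adjusted p = 0.0329 (adjusted p = 0.286 with an estimated correlation). This shift did not pass with median scaling (adjusted p = 0.263), without between-array normalization (adjusted p = 0.271), with scaling on probes above background (adjusted p = 0.284) or without replicate 3 of purified basophils (adjusted p = 0.0583), and over all settings adjusted p was 5.58e-04 to 0.286. T and NK cell markers were higher, with the largest changes in Nkg7 (at least 140.1-fold higher) and Cd3d (at least 1.72-fold higher), though the median was -0.055 with scaling on probes above background. The median of 13 members was 0.29, with 3 higher and 1 lower (4 adjusted over the list alone) and adjusted p = 0.0151 (adjusted p = 0.0833 with an estimated correlation). The list lost its call with median scaling (adjusted p = 0.195), without between-array normalization (adjusted p = 0.151) or with scaling on probes above background (adjusted p = 0.224), and over all settings adjusted p was 1.34e-05 to 0.224.

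The remaining lists did not pass. Haematopoietic transcription factors went both ways, with the largest changes in Ets1 (5.32 ± 0.14), Cebpe (at least 28.5-fold higher), Cebpa (5.05 ± 0.12) and Mitf (-4.92 ± 0.10). In this list 10 of 32 members were higher and 12 lower (24 adjusted over the list alone), at a median of 0.073 and adjusted p = 0.617. Genes of the histamine and eicosanoid pathway went both ways, with the largest changes in Ptgs2 (at least 44.9-fold higher), Alox15 (at least 90.6-fold higher), Hdc (5.82 ± 0.090) and Ltc4s (-4.29 ± 0.094). Of 19 members, 3 were higher and 6 lower (9 adjusted over the list alone), with a median of -0.018 and adjusted p = 0.680. Their mean was 0.26, opposite in sign to the median and to the direction of the test. IgE receptor signalling and exocytosis genes went both ways, with the largest changes in Fyn (3.35 ± 0.21) and Inpp5d (-1.59 ± 0.10). The median of 19 members was -0.18, with 3 higher and 8 lower (11 adjusted over the list alone) and adjusted p = 0.274. Stem and progenitor markers went both ways, with the largest changes in Cd34 (-4.08 ± 0.094) and Mycn (-3.72 ± 0.15). In this list 4 of 10 members were higher and 5 lower (9 adjusted over the list alone), at a median of -0.32 and adjusted p = 0.765. Targets of p53 went both ways, with the largest changes in Btg2 (at least 93.7-fold higher) and Perp (5.51 ± 0.10). Of 18 members, 6 were higher and 8 lower (15 adjusted over the list alone), with a median of -0.10 and adjusted p = 0.865. Their mean was 0.41, opposite in sign to the median and to the direction of the test. B cell markers had Cd79b (3.35 ± 0.10) and Vpreb3 (at least 4.54-fold higher) at the top. The median of 9 members was 0.13, with 3 higher and 0 lower (3 adjusted over the list alone) and adjusted p = 0.113. Limma called no housekeeping gene (1 had an unadjusted p under 0.05). In this list 0 of 8 members were higher and 0 lower (0 adjusted over the list alone), at a median of 0.084 and adjusted p = 0.680.

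The split of cell type calls depended on scaling. It was 8256 higher and 2307 lower without between-array normalization, and 4073 and 12809 with scaling on probes above background. These scalings moved the median of all probes by 0.20 and -0.32 on the log2 scale.

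Floxed and wild type basophils, both with the drug, were compared to find genes that depend on Cebpa. Rimkla, Mgarp, Igsf6, interferon-stimulated and cell cycle genes, among others, also differed without the drug. Cebpa was 33.6-fold lower in the floxed cells (-5.07 ± 0.10, adjusted p = 1.99e-11; 65.1 ± 6.55 against 2704 ± 214, SD, n = 3). Mitf was 3.93-fold higher (1.97 ± 0.081, adjusted p = 4.62e-09), from 417 ± 25.6 in wild type to 1686 ± 98.3. Among the lowest were the immunoglobulin superfamily gene Igsf6 (-5.74 ± 0.085), the tight junction claudin Cldn11 (at least 24.8-fold lower), the interferon-induced Ifit1 (-4.51 ± 0.14), the adhesion molecule Amigo2 (-4.34 ± 0.083) and the neutrophil chemokine receptor Cxcr2 (-4.07 ± 0.076). Among the highest were the growth factor Igf2 (4.51 ± 0.10), Mgarp (4.39 ± 0.12), Rprm (3.83 ± 0.11) and the tryptases Tpsg1 (3.81 ± 0.13) and Tpsb2 (3.78 ± 0.12).

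Igf2 intensity was 2679.9 ± 246 in treated floxed against 102 ± 11.7 in treated wild type cells. Also lower were Nt5e (-3.93 ± 0.079), the interferon-induced Ifi27l2a (-3.90 ± 0.10), F630028O10Rik (-3.85 ± 0.093) and Rimkla (at least 13.8-fold lower). Also higher were Ahi1 (3.24 ± 0.11), Gm5544 (at least 9.09-fold higher) and Ctla2b (3.06 ± 0.091). Plvap was higher too (at least 219-fold higher), whose probe was at background on all 3 wild type arrays with the drug but read 6652 on 1 of 3 without it. So was Dnaja3 (3.78 ± 0.94, and 1.56 to 5.39 over all settings), whose probe read 8, 1 and 505 on the treated wild type arrays; 1 of its 2 other probes did not pass in that direction. Adjusted p over these ranked genes was 0.00840 at most. In all, 7931 probes passed, 4077 higher and 3854 lower in floxed cells, 1414 at least 2-fold. Of higher and lower genes, 30.7% and 34.2% passed the interaction in the same direction.

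Mast cell markers rose, led by Tpsg1 (3.81 ± 0.13) and Tpsb2 (3.78 ± 0.12). Of 18 members, 10 were higher and 1 lower (11 adjusted over the list alone), with a median of 0.76 and adjusted p = 3.11e-04 (adjusted p = 0.0928 with an estimated correlation). The serotonin transporter Slc6a4 fell (-2.82 ± 0.13). Granule proteases rose, led by Tpsg1 (3.81 ± 0.13), Tpsb2 (3.78 ± 0.12), Gzmc (2.17 ± 0.24) and Cma1 (1.32 ± 0.083). The median of 14 members was 0.16, with 6 higher and 2 lower (8 adjusted over the list alone) and adjusted p = 0.0333 (adjusted p = 0.174 with an estimated correlation). No shift was called without between-array normalization (adjusted p = 0.0657) or without replicate 1 of treated floxed cells (adjusted p = 0.0564), and over all settings adjusted p was 9.58e-07 to 0.174. The median was 0.26 without replicate 2 of treated wild type cells and 0.089 without replicate 1 of treated floxed cells. Basophil markers fell, led by Itgam (-2.54 ± 0.092), Il18rap (-1.61 ± 0.088), Itga2 (at least 2.77-fold lower) and Ccl3 (-1.22 ± 0.11). In this list 0 of 14 members were higher and 7 lower (7 adjusted over the list alone), at a median of -0.27 and adjusted p = 0.00212. Mcpt8 did not pass (0.074 ± 0.11, adjusted p = 0.676). Neutrophil granule and maturation genes fell, led by Cxcr2 (-4.07 ± 0.076), Mpo (-3.69 ± 0.095), Prtn3 (-2.83 ± 0.13) and S100a9 (-2.74 ± 0.11). Of 17 members, 3 were higher and 11 lower (15 adjusted over the list alone), with a median of -1.13 (-0.63 with members at background set to their bound) and adjusted p = 3.69e-06.

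Interferon-stimulated genes were lower, led by Ifit1 (-4.51 ± 0.14), Rsad2 (-3.28 ± 0.10), Isg15 (-2.98 ± 0.077) and Ifit2 (-2.91 ± 0.088). The median of 14 members was -1.87, with 0 higher and 12 lower (13 adjusted over the list alone) and adjusted p = 1.45e-12. Monocyte and macrophage markers were lower beside them, with the largest changes in C1qc (-2.57 ± 0.12), Ccr2 (2.45 ± 0.10), Marco (-2.44 ± 0.10) and Mpeg1 (-2.18 ± 0.10). In this list 2 of 14 members were higher and 11 lower (13 adjusted over the list alone), at a median of -1.46 and adjusted p = 3.69e-06. Cx3cr1 (1.60 ± 0.12) was higher like Ccr2. Cell cycle genes were higher, led by Foxm1 (0.95 ± 0.14), Rrm2 (0.92 ± 0.11) and Plk1 (0.92 ± 0.11). Of 24 members, 18 were higher and 0 lower (19 adjusted over the list alone), with a median of 0.56 and adjusted p = 8.37e-08. Cholesterol biosynthesis genes rose, led by Idi1 (1.40 ± 0.10) and Fdft1 (1.19 ± 0.12). The median of 17 members was 0.36, with 8 higher and 0 lower (9 adjusted over the list alone) and adjusted p = 0.00173. Targets of p53 fell, led by Perp (-3.02 ± 0.11), Gadd45a (-2.83 ± 0.083) and Btg2 (-1.90 ± 0.10). In this list 3 of 18 members were higher and 10 lower (14 adjusted over the list alone), at a median of -0.35 and adjusted p = 0.00104.

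Cytokine and chemokine receptors were lower, with the largest changes in Cxcr2 (-4.07 ± 0.076), Il18r1 (-2.83 ± 0.11), Ccr2 (2.45 ± 0.10) and Il7r (-2.34 ± 0.080). Of 25 members, 7 were higher and 13 lower (22 adjusted over the list alone), with a median of -0.55 (-0.50 with members at background set to their bound) and adjusted p = 0.00734 (adjusted p = 0.0901 with an estimated correlation). Il18r1 is a receptor chain of interleukin-18 and Il7r of interleukin-7. Stem and progenitor markers rose, led by Cd34 (1.40 ± 0.088) and Erg (at least 1.55-fold higher). The median of 10 members was 0.32, with 6 higher and 1 lower (7 adjusted over the list alone) and adjusted p = 0.0206 (adjusted p = 0.0824 with an estimated correlation). MHC class II and costimulation genes fell, led by Cd86 (-2.09 ± 0.10) and H2-Aa (-1.07 ± 0.10). In this list 1 of 11 members was higher and 6 lower (7 adjusted over the list alone), at a median of -0.49 and adjusted p = 0.00734 (adjusted p = 0.140 with an estimated correlation). Immediate early and handling genes fell, led by Zfp36 (-1.84 ± 0.083) and Fos (-1.67 ± 0.11). Of 16 members, 3 were higher and 7 lower (11 adjusted over the list alone), with a median of -0.26 and adjusted p = 0.0198 (adjusted p = 0.0928 with an estimated correlation). Haematopoietic transcription factors went both ways without a shift of the list, with the largest changes in Cebpa (-5.07 ± 0.10), Tfec (-2.09 ± 0.078), Mitf (1.97 ± 0.081) and Myb (1.91 ± 0.094). The median of 32 members was -0.21, with 11 higher and 14 lower (27 adjusted over the list alone) and adjusted p = 0.202. The lists of IgE receptor signalling, cytokines, the histamine and eicosanoid pathway and housekeeping genes did not pass, nor did those of eosinophil, B cell, T and NK cell, erythroid and megakaryocyte markers (lowest adjusted p = 0.0755). Their signs differed for IgE receptor signalling (median -0.064, mean 0.010, test downward) and T and NK cell markers (median 0.023, mean -0.10, test downward).

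Calls split into 4796 higher and 2936 lower without between-array normalization, and 3601 and 5016 with scaling on probes above background. Several named genes have close relatives (tryptases, chymases, Ifi27l2 genes), and whether their probes cross-hybridize was not tested.

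**Figure D2:**
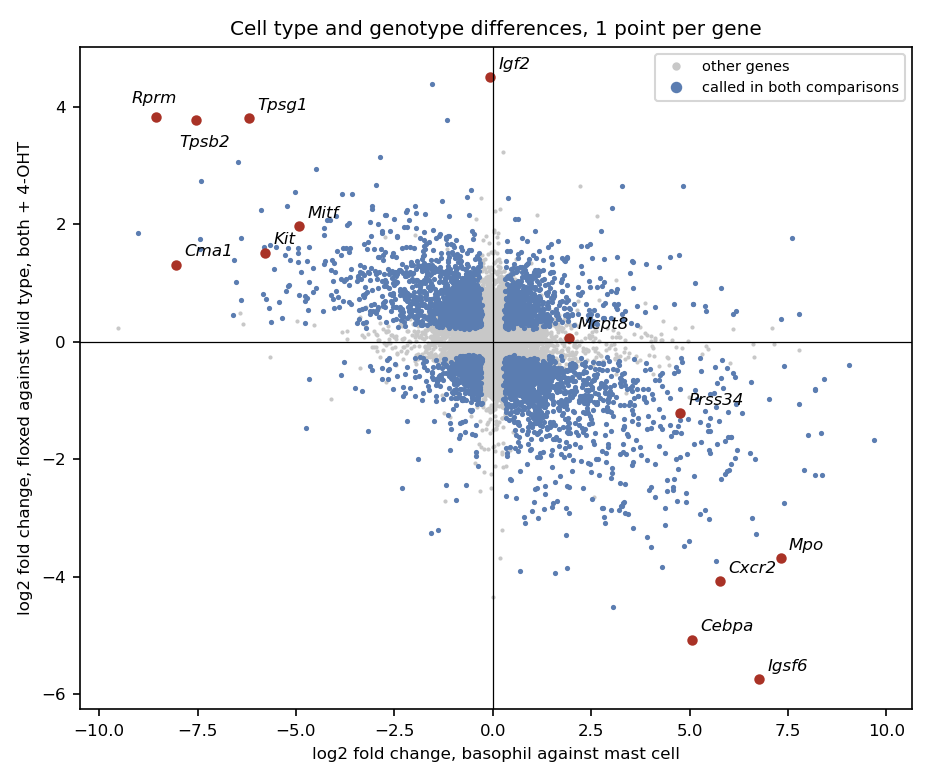
Each point is a gene, with its log2 fold change between basophils and mast cells (horizontal) and between treated floxed and wild type basophils (vertical); genes at background in both groups of either comparison are left out, blue points passed both tests, and red points are genes with their name. Tryptases and Mitf lie at the upper left and Cebpa, Igsf6, Cxcr2 and Mpo at the lower right; Pearson's r across 11921 genes was -0.399.

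Genes differing between basophils and mast cells, by cell type, culture or admixed marrow cells, were tested in treated floxed cells on other arrays. Of 1556 genes at least 2-fold higher in basophils, 757 were lower in treated floxed basophils (252 expected from independent lists) and 248 higher (278 expected). Of 1309 genes at least 2-fold higher in mast cells, 661 were higher (234 expected) and 110 lower (212 expected). The median shifts were -0.33 and 0.37 on the log2 scale (camera adjusted p = 2.05e-13 and 4.64e-16, or 8.91e-06 for both with an estimated correlation). In the wild type, the drug shifted the same sets by -0.044 and 0.029 (camera adjusted p = 0.162 and 0.445). Without the drug the sets already differed between the genotypes, by -0.13 and 0.080 (adjusted p = 1.56e-04 and 0.00324 with an estimated correlation), with 467 basophil-higher genes lower (123 expected) and 235 higher (146 expected). Of the mast cell-higher genes, 295 were higher (123 expected) and 128 lower (103 expected). Expected counts here and below include genes at background and may be too low. Within floxed cells the drug shifted both sets by -0.24 and 0.30 (adjusted p = 8.91e-06 for both with an estimated correlation). Across 11921 genes, the fold changes of both comparisons had Pearson's r = -0.399 and Spearman's rho = -0.258; genes are not independent replicates.

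Floxed basophils with and without the drug give the deletion within a genotype, together with any effect of the drug itself. Cebpa fell 11.9-fold (-3.58 ± 0.10, adjusted p = 5.96e-10), from 949 ± 61.3 to 65.1 ± 6.55 (SD, n = 3), and Mitf rose 4.18-fold (2.06 ± 0.081, adjusted p = 7.47e-09). Igf2 (4.53 ± 0.10), Mcpt2 (4.37 ± 0.19), Tpsg1 (3.59 ± 0.13), Ahi1 (3.23 ± 0.11) and Kit, the stem cell factor receptor (3.16 ± 0.10, from 1472 to 13323), rose most. Mcpt2 rose from 45.3 to 1259, near its level in treated wild type cells (1045). Cldn11 (at least 17.1-fold lower), the ubiquitin ligase Hecw2 (-3.61 ± 0.12), the coagulation factor F13a1 (-3.56 ± 0.093) and Cxcr2 (-3.50 ± 0.076) fell most beside Cebpa.

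Adjusted p over these genes was 1.91e-08 at most. In all, 4925 probes passed, 2491 higher and 2434 lower, and 655 of them changed at least 2-fold. Neutrophil granule and maturation genes fell, led by Cxcr2 (-3.50 ± 0.076), Prtn3 (-2.53 ± 0.13) and Mpo (-2.52 ± 0.095). In this list 0 of 17 members were higher and 9 lower (11 adjusted over the list alone), at a median of -0.47 (-0.34 with members at background set to their bound) and adjusted p = 7.30e-08. Megakaryocyte and platelet markers rose, led by Ppbp (1.62 ± 0.11) and Pf4 (1.00 ± 0.13). Of 8 members, 7 were higher and 0 lower (7 adjusted over the list alone), with a median of 0.73 and adjusted p = 9.30e-06. Mast cell markers rose, led by Mcpt2 (4.37 ± 0.19), Tpsg1 (3.59 ± 0.13) and Kit (3.16 ± 0.10). The median of 18 members was 0.79, with 10 higher and 2 lower (12 adjusted over the list alone) and adjusted p = 7.30e-08 (adjusted p = 0.0561 with an estimated correlation). Granule proteases rose, led by Mcpt2 (4.37 ± 0.19), Tpsg1 (3.59 ± 0.13), Tpsb2 (3.07 ± 0.12) and Cma1 (2.15 ± 0.083). In this list 8 of 14 members were higher and 2 lower (10 adjusted over the list alone), at a median of 1.12 and adjusted p = 2.80e-05 (adjusted p = 0.0561 with an estimated correlation). Interferon-stimulated genes did not pass. Of 14 members, 0 were higher and 3 lower (3 adjusted over the list alone), with a median of -0.021 and adjusted p = 0.506. Cell cycle genes did not pass either. The median of 24 members was -0.14, with 2 higher and 5 lower (11 adjusted over the list alone) and adjusted p = 0.193. Macrophage markers did not pass. In this list 6 of 14 members were higher and 5 lower (11 adjusted over the list alone), at a median of 0.025 and adjusted p = 0.628. Nor did basophil markers. Of 14 members, 2 were higher and 6 lower (10 adjusted over the list alone), with a median of 0.0043 and adjusted p = 0.220. Median, mean and test differed in sign, with no call, for interferon-stimulated genes (median -0.021, mean 0.0077, test downward), basophil markers (median 0.0043, mean -0.26, test downward), eosinophil markers (median 0.015, mean -0.0053, test upward) and p53 targets (median 0.12, mean -0.16, test downward). Other scalings gave 1353 higher and 2185 lower (median scaling) and 2077 higher and 3154 lower (probes above background).

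Wild type basophils with and without the drug show the effect of 4-hydroxytamoxifen and of the active recombinase with no floxed allele. Cebpa did not pass (0.23 ± 0.10, adjusted p = 0.147; 2306 ± 198 without and 2704 ± 214 with the drug, SD, n = 3), and its value was -0.080 without between-array normalization. Mitf fell 1.35-fold (-0.44 ± 0.081, adjusted p = 0.00242). The 28S ribosomal RNA gene Rn28s1 (1.84 ± 0.15), the platelet chemokine Ppbp (1.82 ± 0.11), AB124611 (1.77 ± 0.11), Amigo2 (1.69 ± 0.083) and the RNA-binding protein Raly (1.62 ± 0.075) rose most; the other probe of Raly did not pass in that direction. Bpifc (at least 9.46-fold lower), Retnlg (-2.87 ± 0.11; 12209 to 1655), the glutamate receptor subunit Gria3 (-2.65 ± 0.11), the zinc transporter Slc39a8 (at least 5.64-fold lower) and Gm4956 (-2.60 ± 0.089) fell most.

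Adjusted p over these genes was 1.21e-05 at most. The drug changed 5396 probes, 2834 higher and 2562 lower, of which 307 changed at least 2-fold. Targets of p53 rose with the drug, led by Phlda3 (1.45 ± 0.10), Gadd45a (0.94 ± 0.083) and Btg2 (0.73 ± 0.10). The median of 18 members was 0.31, with 8 higher and 1 lower (12 adjusted over the list alone) and adjusted p = 0.0141 (adjusted p = 0.152 with an estimated correlation). It did not pass with median scaling (adjusted p = 0.134), without between-array normalization (adjusted p = 0.0765) or with scaling on probes above background (adjusted p = 0.0831), and over all settings adjusted p was 9.24e-06 to 0.152. Cholesterol biosynthesis genes fell, led by Fdft1 (-1.05 ± 0.12), Idi1 (-0.86 ± 0.10) and Cyp51 (-0.60 ± 0.087). In this list 0 of 17 members were higher and 6 lower (6 adjusted over the list alone), at a median of -0.20 and adjusted p = 0.00843 (adjusted p = 0.109 with an estimated correlation). Immediate early and handling genes rose, led by Fos (0.94 ± 0.11) and Zfp36 (0.78 ± 0.083). Of 16 members, 5 were higher and 0 lower (6 adjusted over the list alone), with a median of 0.23 and adjusted p = 0.00587 (adjusted p = 0.109 with an estimated correlation). This shift did not pass with scaling on probes above background (adjusted p = 0.0551), and over all settings adjusted p was 2.06e-05 to 0.109. Megakaryocyte and platelet markers rose, led by Ppbp (1.82 ± 0.11) and Gp1bb (0.90 ± 0.087). The median of 8 members was 0.30, with 4 higher and 0 lower (4 adjusted over the list alone) and adjusted p = 0.0148 (adjusted p = 0.109 with an estimated correlation). The list lost its call with scaling on probes above background (adjusted p = 0.0551), and over all settings adjusted p was 9.24e-06 to 0.109. No list passed with an estimated correlation (4 had an unadjusted camera p under 0.05, and fry called 12). Among lists without a call, the signs of median, mean and test differed for granule proteases (median 0.045, mean -0.067, test downward), neutrophil granule and maturation genes (median -0.0048, mean 0.091, test upward), monocyte and macrophage markers (median 0.071, mean -0.13, test downward) and interferon-stimulated genes (median 0.017, mean -0.16, test upward). Without between-array normalization the probes split into 1359 higher and 4681 lower.

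Untreated floxed and wild type basophils differ in genotype without the drug that activates the recombinase. Cebpa was already 2.40-fold lower in the floxed cells (-1.26 ± 0.10, adjusted p = 4.67e-06; 949 ± 61.3 against 2306 ± 198, SD, n = 3). Mitf was lower too (-0.52 ± 0.081, adjusted p = 8.07e-04, and 0.0588 with median scaling, the highest of a range from 2.50e-05 over all settings). Ifit1 (-4.09 ± 0.14), Ifi27l2b (-3.31 ± 0.10), Rimkla (-3.31 ± 0.12), the cytotoxic protease Gzma (-3.17 ± 0.088) and the complement component C1qb (-3.13 ± 0.19) were lowest. The channel gene Pkd2l1 (2.94 ± 0.14) and Mgarp (2.66 ± 0.12) were among the highest, beside Mrpl46 (at least 48.2-fold higher), Plvap (6.26 ± 1.71) and Foxj1 (2.71 ± 0.78), whose probes switched between background and bright within at least 1 group.

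Adjusted p was 0.0363 at most over these genes, and 4.00e-07 without Mrpl46, Plvap and Foxj1. Those 3 genes lost their calls when the variance was modelled with an intensity trend (adjusted p = 0.0694, 0.0784 and 0.0953) and, for Mrpl46, when any of the 6 arrays was left out. Plvap and Foxj1 lost them without any but replicate 3 of untreated wild type cells. Over all settings adjusted p was 1.17e-07 to 0.0790 for Mrpl46, 5.45e-10 to 0.112 for Plvap and 0.00295 to 0.137 for Foxj1. The log2 fold change was 4.66 to 9.16 for Plvap and 1.98 to 3.68 for Foxj1 over the same settings. In all, 3927 probes passed, 2121 higher and 1806 lower in floxed cells, and 473 differed at least 2-fold. Without the drug the calls split into 2086 higher and 916 lower with median scaling and 1392 higher and 2752 lower without normalization.

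Interferon-stimulated genes were lower in floxed cells, led by Ifit1 (-4.09 ± 0.14), Rsad2 (-2.93 ± 0.10) and Ifit2 (-2.84 ± 0.088). In this list 0 of 14 members were higher and 13 lower (14 adjusted over the list alone), at a median of -2.18 and adjusted p = 2.73e-22. Monocyte and macrophage markers were lower beside them, led by C1qb (-3.13 ± 0.19), C1qa (-2.87 ± 0.084) and C1qc (-2.71 ± 0.12). Of 14 members, 1 was higher and 12 lower (13 adjusted over the list alone), with a median of -1.36 and adjusted p = 7.33e-12. Adgre1 of that list was higher (0.86 ± 0.12). Cell cycle genes were higher, led by Ccnb2 (1.19 ± 0.15), Rrm2 (1.04 ± 0.11) and Mki67 (0.96 ± 0.10). The median of 24 members was 0.71, with 22 higher and 0 lower (22 adjusted over the list alone) and adjusted p = 7.97e-18. Cholesterol biosynthesis genes were higher, led by Stard4 (0.64 ± 0.078) and Idi1 (0.56 ± 0.10). In this list 6 of 17 members were higher and 0 lower (8 adjusted over the list alone), at a median of 0.11 and adjusted p = 0.00814. Their median became 0.19 without replicate 1 of untreated wild type cells, 0.18 without replicate 3 of untreated wild type cells and 0.19 without replicate 1 of untreated floxed cells. Haematopoietic transcription factors were lower, with the largest changes in Cebpa (-1.26 ± 0.10), Gfi1b (-0.65 ± 0.090) and Lyl1 (-0.58 ± 0.086). Of 32 members, 2 were higher and 16 lower (22 adjusted over the list alone), with a median of -0.32 and adjusted p = 1.36e-05. Megakaryocyte and platelet markers were lower, led by Pf4 (-1.25 ± 0.13) and Treml1 (-0.69 ± 0.092). The median of 8 members was -0.63, with 0 higher and 5 lower (6 adjusted over the list alone) and adjusted p = 1.06e-04.

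Cytokine and chemokine receptors were lower, with the largest changes in Il2ra (2.02 ± 0.14) and Il18r1 (-1.61 ± 0.11). In this list 4 of 25 members were higher and 12 lower (16 adjusted over the list alone), at a median of -0.31 (-0.22 with members at background set to their bound) and adjusted p = 6.79e-04. Cytokines and chemokines were lower, led by Ccl7 (-2.28 ± 0.083) and Ccl2 (-1.93 ± 0.13), though the median was 0.0095 with median scaling. Of 24 members, 2 were higher and 7 lower (11 adjusted over the list alone), with a median of -0.10 and adjusted p = 0.00814. These 8 lists also passed with an estimated correlation, and further lists passed with the preset correlation alone. Neutrophil granule and maturation genes were lower, with the largest changes in Ltf (-1.75 ± 0.093) and S100a9 (-1.36 ± 0.11). The median of 17 members was -0.26, with 3 higher and 6 lower (11 adjusted over the list alone) and adjusted p = 0.0131 (adjusted p = 0.0679 with an estimated correlation). Members had a median of -0.17 without replicate 3 of untreated wild type cells. Eosinophil markers were lower, with the largest changes in Alox15 (-1.73 ± 0.089) and Ccr3 (-1.19 ± 0.13). In this list 1 of 7 members was higher and 4 lower (5 adjusted over the list alone), at a median of -0.69 (-0.22 with members at background set to their bound) and adjusted p = 0.0308 (adjusted p = 0.126 with an estimated correlation). B cell markers were lower, led by Vpreb3 (-1.63 ± 0.090) and Vpreb1 (-0.32 ± 0.083). Of 9 members, 0 were higher and 2 lower (3 adjusted over the list alone), with a median of -0.25 and adjusted p = 0.0259 (adjusted p = 0.0755 with an estimated correlation). It did not pass without replicate 2 of untreated floxed cells (adjusted p = 0.0570), and over all settings adjusted p was 1.24e-05 to 0.0755.

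Stem and progenitor markers were higher, with the largest changes in Cd34 (1.45 ± 0.088) and Hoxa9 (0.86 ± 0.10). The median of 10 members was 0.19, with 3 higher and 1 lower (5 adjusted over the list alone) and adjusted p = 0.0259 (adjusted p = 0.0755 with an estimated correlation). This shift did not pass with median scaling (adjusted p = 0.0542), and over all settings adjusted p was 1.98e-06 to 0.0755. Members had a median of 0.36 without replicate 1 of untreated floxed cells. Targets of p53 were lower, with the largest changes in Gadd45a (-1.01 ± 0.083) and Polk (0.78 ± 0.087). In this list 2 of 18 members were higher and 5 lower (7 adjusted over the list alone), at a median of -0.15 and adjusted p = 0.0193 (adjusted p = 0.0895 with an estimated correlation). MHC class II and costimulation genes were lower, led by Cd86 (-1.04 ± 0.10) and H2-Aa (-0.60 ± 0.10). Of 11 members, 0 were higher and 3 lower (3 adjusted over the list alone), with a median of -0.16 and adjusted p = 0.0259 (adjusted p = 0.201 with an estimated correlation). No shift was called without replicate 2 of untreated wild type cells (adjusted p = 0.0519) or without replicate 2 of untreated floxed cells (adjusted p = 0.0623), and over all settings adjusted p was 0.00116 to 0.201. Their median became -0.082 without replicate 2 of untreated wild type cells, -0.26 without replicate 1 of untreated floxed cells and -0.10 without replicate 2 of untreated floxed cells. Basophil markers were lower, with the largest changes in Ifitm1 (-0.98 ± 0.086) and Ccl3 (-0.62 ± 0.11), though the median was 0.070 with median scaling. The median of 14 members was -0.088, with 1 higher and 4 lower (6 adjusted over the list alone) and adjusted p = 0.0308 (adjusted p = 0.0755 with an estimated correlation). It did not pass with median scaling (adjusted p = 0.215), without between-array normalization (adjusted p = 0.153) or with scaling on probes above background (adjusted p = 0.156), and over all settings adjusted p was 2.09e-05 to 0.215. Mast cell markers were lower, with the largest changes in Mcpt2 (-3.10 ± 0.19) and Slc6a4 (-1.07 ± 0.13), though the median was 0.11 with median scaling. In this list 1 of 18 members was higher and 6 lower (8 adjusted over the list alone), at a median of -0.039 and adjusted p = 0.0329 (adjusted p = 0.276 with an estimated correlation). This shift did not pass with median scaling (adjusted p = 0.0657), without between-array normalization (adjusted p = 0.153), with scaling on probes above background (adjusted p = 0.122) or without replicate 1 of untreated floxed cells (adjusted p = 0.123), and over all settings adjusted p was 9.86e-04 to 0.276. Their median became -0.085 without replicate 1 of untreated wild type cells and -0.13 without replicate 2 of untreated floxed cells. Granule proteases were lower, led by Gzma (-3.17 ± 0.088) and Mcpt2 (-3.10 ± 0.19), though the median was 0.23 with median scaling, 0.042 without between-array normalization, 0.11 with scaling on probes above background and 0.0087 without replicate 3 of untreated wild type cells. Of 14 members, 0 were higher and 4 lower (4 adjusted over the list alone), with a median of -0.026 and adjusted p = 0.0259 (adjusted p = 0.173 with an estimated correlation). No shift was called with median scaling (adjusted p = 0.0657), without between-array normalization (adjusted p = 0.190), with scaling on probes above background (adjusted p = 0.156) or without replicate 1 of untreated floxed cells (adjusted p = 0.0754), and over all settings adjusted p was 8.48e-06 to 0.190. The median was -0.069 without replicate 1 of untreated wild type cells, -0.050 without replicate 2 of untreated wild type cells, -0.047 without replicate 1 of untreated floxed cells and -0.063 without replicate 2 of untreated floxed cells. Signs differed, with no call, for the histamine and eicosanoid pathway (median 0.047, mean -0.0051, test upward) and erythroid markers (median -0.079, mean 0.055, test upward).

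Of the genes higher in floxed cells without the drug, 1247 were also higher with it (319 expected from independent lists of 1790 and 3405 of 19084 genes), and 1052 were lower in both (245 expected from 1508 and 3096). These comparisons share genotypes but no arrays.

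**Figure D3:**
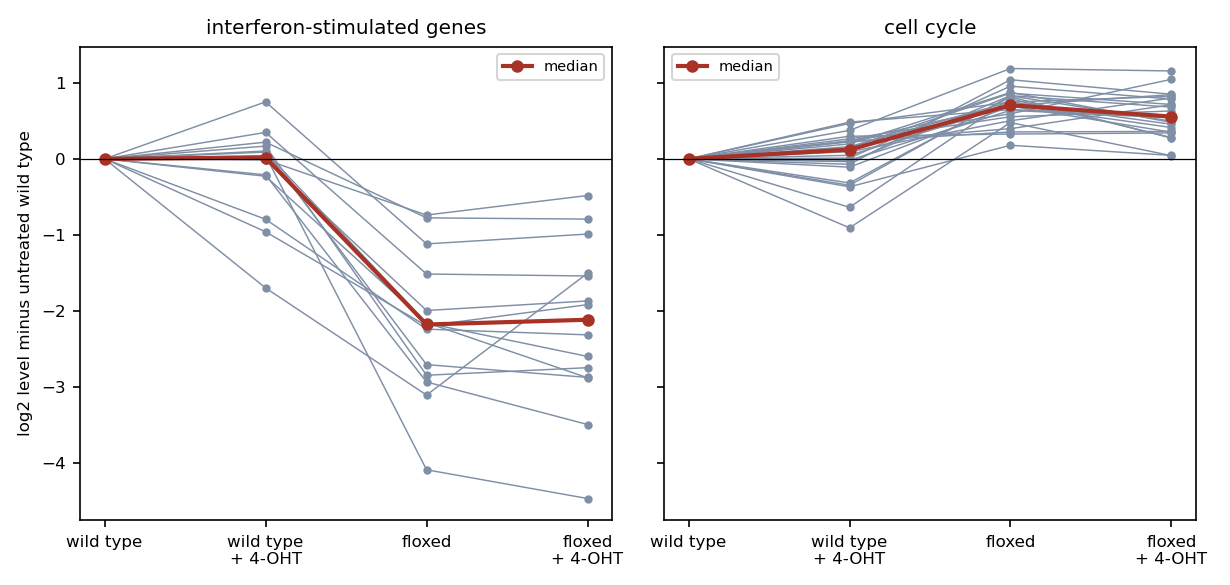
Mean log2 level of each interferon-stimulated gene (left) and each cell cycle gene (right) in the 4 cultured basophil groups, minus its level in untreated wild type cells; thin lines are genes and the thick line is the median. In floxed cells the median of interferon-stimulated genes was lower and that of cell cycle genes higher, with and without the drug.

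The interaction of genotype and drug tests whether 4-hydroxytamoxifen acted differently in floxed and wild type basophils. Cebpa had a more negative drug effect in floxed cells (-3.80 ± 0.14, adjusted p = 3.04e-08, n = 3 in each of 4 groups), and Mitf a more positive one (2.50 ± 0.12, adjusted p = 9.91e-08). The tryptases Tpsg1 (4.44 ± 0.18) and Tpsb2 (4.00 ± 0.17), Igf2 (4.13 ± 0.14), the secreted chloride channel regulator Clca1 (3.73 ± 0.14) and Mcpt2 (3.34 ± 0.27) had the most positive differences. Cldn11 (at least 18.9-fold, with treated floxed cells at background), Nt5e (-4.17 ± 0.11), Igsf6 (-3.47 ± 0.12) and the neutrophil granule enzyme Mpo (-3.42 ± 0.13) had the most negative beside Cebpa.

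Adjusted p over these genes was 1.06e-05 at most. The drug effect differed between genotypes for 2976 probes, 1442 higher and 1534 lower, with at least a 2-fold difference for 673. Neutrophil granule and maturation genes had a more negative drug effect in floxed cells, led by Mpo (-3.42 ± 0.13), Cxcr2 (-3.26 ± 0.11) and Prtn3 (-3.09 ± 0.18). The median of 17 members was -0.55, with 0 higher and 7 lower (8 adjusted over the list alone) and adjusted p = 4.72e-07. Mast cell markers had a more positive drug effect, led by Tpsg1 (4.44 ± 0.18) and Tpsb2 (4.00 ± 0.17). In this list 11 of 18 members were higher and 2 lower (13 adjusted over the list alone), at a median of 0.68 and adjusted p = 1.09e-06 (adjusted p = 0.0679 with an estimated correlation). Granule proteases had a more positive drug effect, led by Tpsg1 (4.44 ± 0.18), Tpsb2 (4.00 ± 0.17), Mcpt2 (3.34 ± 0.27) and Gzma (3.16 ± 0.12). Of 14 members, 8 were higher and 2 lower (10 adjusted over the list alone), with a median of 0.68 and adjusted p = 6.50e-05 (adjusted p = 0.0679 with an estimated correlation). Basophil markers had a more negative drug effect, led by Itgam (-2.09 ± 0.13), Il18rap (-1.61 ± 0.12) and Itga2 (at least 2.57-fold lower). The median of 14 members was -0.20, with 1 higher and 6 lower (7 adjusted over the list alone) and adjusted p = 0.0105 (adjusted p = 0.0679 with an estimated correlation). Targets of p53 had a more negative drug effect, led by Perp (-2.35 ± 0.16) and Gadd45a (-1.82 ± 0.12), though the median was 0.072 without between-array normalization. In this list 1 of 18 members was higher and 5 lower (6 adjusted over the list alone), at a median of -0.15 and adjusted p = 0.00695 (adjusted p = 0.103 with an estimated correlation). Interferon-stimulated genes did not pass. Of 14 members, 1 was higher and 1 lower (6 adjusted over the list alone), with a median of -0.25 and adjusted p = 0.330. Their mean was 0.16, with the test downward. Signs differed too, with no call, for haematopoietic transcription factors (median -0.065, mean 0.025, test upward) and B cell markers (median -0.14, mean 0.12, test downward).

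Cholesterol biosynthesis genes had a more positive drug effect in floxed cells, led by Idi1 (0.84 ± 0.14) and Fdps (0.79 ± 0.18). The median of 17 members was 0.21, with 4 higher and 0 lower (5 adjusted over the list alone) and adjusted p = 0.0353 (adjusted p = 0.110 with an estimated correlation). It did not pass with median scaling (adjusted p = 0.0762), without replicate 2 of treated wild type cells (adjusted p = 0.0572), without replicate 2 of untreated wild type cells (adjusted p = 0.0590) or without replicate 3 of treated floxed cells (adjusted p = 0.0745), and over all settings adjusted p was 9.97e-04 to 0.110. Members had a median of 0.12 without replicate 2 of treated wild type cells, 0.13 without replicate 3 of treated floxed cells and 0.14 without replicate 3 of untreated floxed cells. MHC class II and costimulation genes had a more negative drug effect, led by Cd86 (-1.05 ± 0.14) and Cd74 (-0.80 ± 0.11). In this list 0 of 11 members were higher and 3 lower (4 adjusted over the list alone), at a median of -0.30 and adjusted p = 0.0353 (adjusted p = 0.286 with an estimated correlation). The list lost its call with median scaling (adjusted p = 0.0949), without between-array normalization (adjusted p = 0.0689), with scaling on probes above background (adjusted p = 0.0820), without replicate 2 of treated wild type cells (adjusted p = 0.0637), without replicate 3 of untreated wild type cells (adjusted p = 0.0747), without replicate 2 of treated floxed cells (adjusted p = 0.0532) or without replicate 1 of untreated floxed cells (adjusted p = 0.0908), and over all settings adjusted p was 0.00329 to 0.286. Immediate early and handling genes had a more negative drug effect, led by Hspa1b (-1.25 ± 0.16) and Zfp36 (-0.80 ± 0.12), though the median was 0.020 without between-array normalization. Of 16 members, 0 were higher and 5 lower (7 adjusted over the list alone), with a median of -0.16 and adjusted p = 0.0353 (adjusted p = 0.166 with an estimated correlation). No shift was called with median scaling (adjusted p = 0.0861), without between-array normalization (adjusted p = 0.0948), with scaling on probes above background (adjusted p = 0.104), without replicate 3 of untreated wild type cells (adjusted p = 0.0556), without replicate 3 of treated floxed cells (adjusted p = 0.0623) or without replicate 2 of untreated floxed cells (adjusted p = 0.0781), and over all settings adjusted p was 2.48e-04 to 0.166.

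Of genes higher in basophils, 405 had a more negative drug effect in floxed cells (102 expected; median -0.20, camera adjusted p = 2.01e-05 with an estimated correlation). Of genes higher in mast cells, 373 had a more positive drug effect (83.9 expected; median 0.28, camera adjusted p = 8.91e-06 with an estimated correlation). Other scalings gave 1582 calls, 515 higher and 1067 lower (median scaling), and 2643 higher and 701 lower (no normalization).

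**Figure D4:**
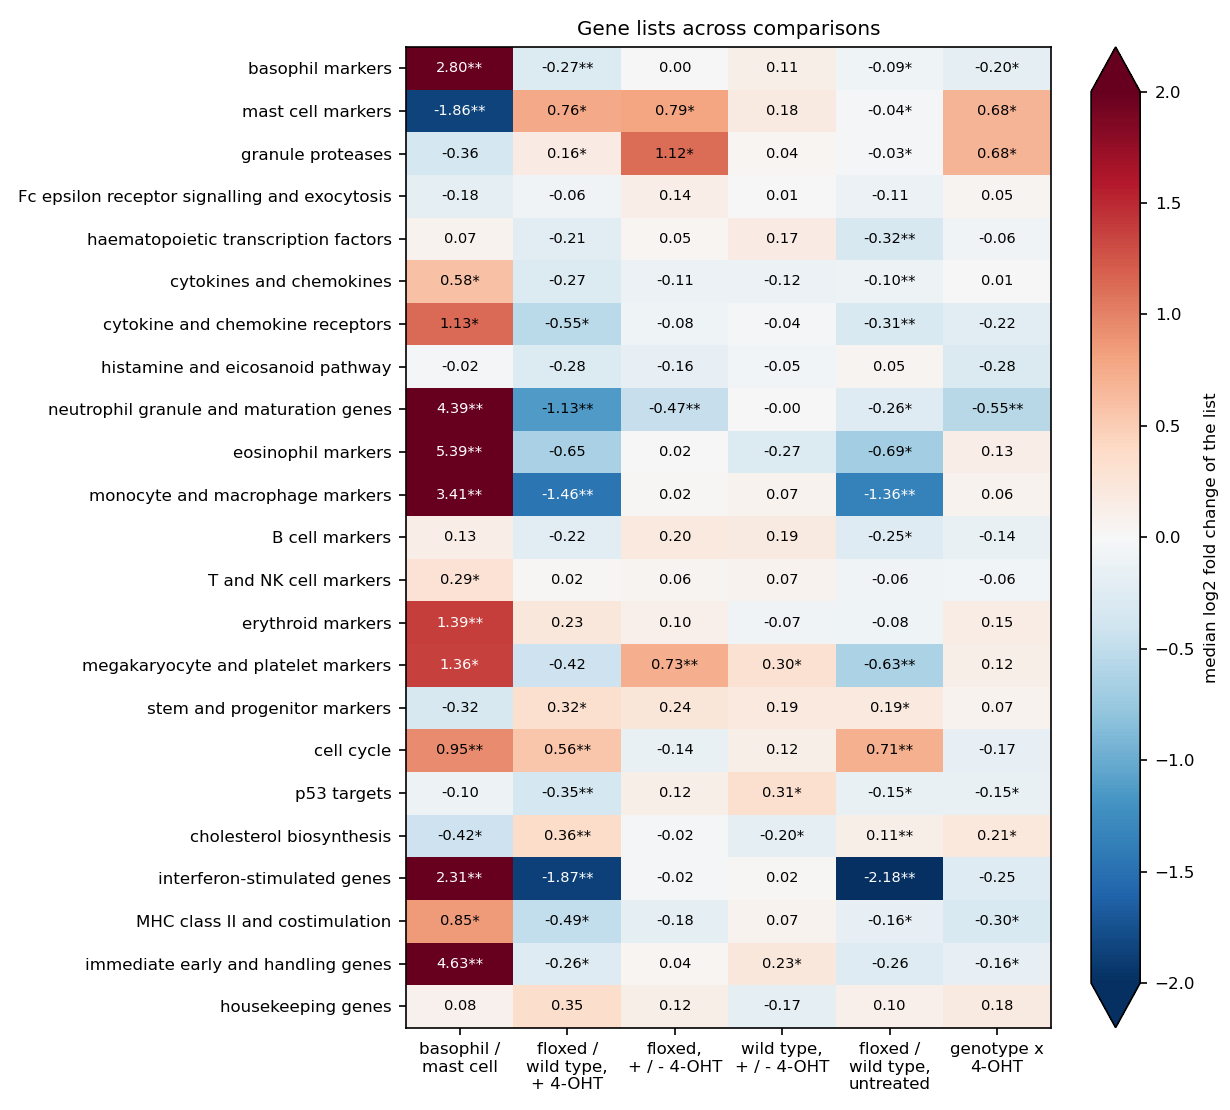
Median log2 fold change of the 23 gene lists in each of the 6 comparisons; 1 star marks camera adjusted p under 0.05 with the preset correlation and a second star that the call also held with an estimated correlation. The neutrophil list carries both stars in 4 of the comparisons, higher in basophils than in mast cells (4.39), lower in treated floxed than in treated wild type cells (-1.13), lower with the drug in floxed cells (-0.47) and more negative in the interaction (-0.55), and 1 star between the genotypes without the drug (-0.26).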

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

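In this part the interaction, the list tests with an estimated correlation, median scaling and the counts over other splits of the arrays were planned. The other scalings and the tests of recombination, macrophages, loss of Cebpa and other probes of a gene were chosen after the result was seen. The results below stood out because the effect of the drug differed between floxed and wild type basophils by a test of the interaction. They are the 2976 probes that passed it, and Tpsg1 (4.44 log2), Igf2 (4.13), Tpsb2 (4.00), Clca1 (3.73), Mcpt2 (3.34) and Mitf (2.50) with a more positive drug effect in floxed cells. The effect was more negative there for Cldn11 (at least 18.9-fold, with treated floxed cells at background), Nt5e (-4.17), Cebpa (-3.80), Igsf6 (-3.47) and Mpo (-3.42). Median differences were 0.68 for mast cell markers, 0.68 for granule proteases and 0.21 for cholesterol biosynthesis (0.12 to 0.26 with an array left out). They were -0.20 for basophil markers, -0.55 for neutrophil genes, -0.15 for p53 targets, -0.30 for MHC class II and costimulation and -0.16 for immediate early genes. Of these lists, neutrophil genes alone kept the call with an estimated correlation, and those of cholesterol, MHC class II and immediate early genes also lost it with single arrays left out. Genes higher in basophils shifted by -0.20 and genes higher in mast cells by 0.28.

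Of 100 drawn splits of the drug label within each genotype, 2 gave as many interaction calls and 1 as many lists, the real one included. The real one gave 2976 calls and 8 lists, the highest others 6819 and 6. Most splits break up the drug effects, so this cannot exclude chance. The split with 6819 calls exchanged every wild type drug label, adding both drug effects. The next gave 1302. For the shifts of basophil-higher and mast cell-higher genes, 12 and 11 of the 100 splits were as large (real 0.20 and 0.28 in size, highest other 0.30 and 0.34). The others as large were all among the 11 that kept or exchanged every floxed drug label, leaving that drug effect in place. Neither shift can thus give a share under 0.05. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. In each case only the real one was as large. Fitted on the 6 arrays compared, the real calls and the highest of the other splits were 9988 and 1 for basophils against mast cells, 7018 and 2 for treated floxed against wild type cells, and 3194 and 2 for untreated ones. For the drug they were 3766 and 3 in floxed and 4935 and 1 in wild type cells. The lists called were 15 and 11, 13 and 4, 17 and 6, 4 and 1, and 4 and 1 in the same order. The sets shifted in treated floxed cells by 0.33 and 0.36 in size, against 0.14 and 0.16 at most in the others.

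Cebpa was 2.40-fold lower in floxed than in wild type basophils without the drug. Under 3 other scalings its log2 fold change stayed between -1.36 and -1.17, which argues against array scaling as the cause. Recombination without the drug in 60.3% of cells would give that level, and the mixture of deleted and undeleted cells predicts a median of 0.92 for mast cell-higher genes that were raised in treated floxed cells, against 0.42 observed (SD over arrays 0.036; Mitf predicted 1.47, observed -0.52; Kit predicted 1.09, observed -0.55). Basophil-higher genes that were lower in treated floxed cells moved by -0.75 at the median against -0.73 predicted, but 65.3% of these 326 genes lay over 2 SE from their own prediction (Mpo predicted -1.17, observed -0.26 ± 0.095, Igsf6 predicted -1.29, observed -2.27 ± 0.085 and Cxcr2 predicted -1.21, observed -0.82 ± 0.076), which argues against the mixture as the whole cause in either set. A mixture beside other differences between the genotypes, a lower Cebpa level from the unrecombined floxed allele, and deletion too recent for the mast cell genes to rise, stay open and were not tested.

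Interferon-stimulated genes were lower in floxed basophils with and without the drug. Other scalings left their median without the drug between -2.30 and -2.11, and floxed cells with against without the drug differed by -0.021 (SD 0.114), which argues against array scaling and against loss of Cebpa during the drug treatment as the cause. Macrophage markers fell beside them (median -1.36, SD over markers 1.16; C1qa from 1582 to 203 and Mrc1 from 2479 to 709.6), so fewer macrophages may contribute, although the labels call the cells purified and Adgre1 rose from 3291 to 6004. With 3 of 14 markers down as far as these genes, 6 above background in mast cells and 2 in other lists, this cannot be told apart from a change in the basophils. Genotype coincides with any batch of mice or cultures and cannot be told apart from it, and an effect of the floxed genotype itself stays open, untested.

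Single probes switched from background to bright between arrays of the same group: 51 probes (0.193%), 32 of them in 1 group alone. If the samples themselves differed, other probes of the same genes would switch too. Over 8 genes in 18 pairs of gene and group, those other probes (21 pairs of probes) differed by 0.029 at the median (SD 0.187) between the dim and the bright arrays, while the switching probes differed by -4.90. That argues against a difference between the samples for these 8 genes and leaves failed spots on single arrays as a candidate explanation. Plvap, Mrpl46 and Foxj1 have no other probe, so their differences stay open.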

How the results depend on the processing

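The alternatives without between-array normalization, with scaling on probes above background, with only probes above background and without switching probes were chosen after the data were seen. Values follow the order basophils against mast cells, treated floxed against wild type, the drug in floxed cells, the drug in wild type cells, untreated floxed against wild type, and the interaction. Requiring at least 2-fold left 3449, 1414, 655, 307, 473 and 673 probes, a stricter threshold by construction. Scaling on probes above background gave 16882 calls between the cell types against 9988, and median scaling 1582 interaction calls against 2976; the cause was not tested. An estimated correlation left 9, 7, 2, 0, 8 and 1 lists against 15, 13, 4, 4, 17 and 8; the cause was not tested. Fry, which does not compare a list with other genes, called 22, 17, 12 and 17 lists (treated genotypes, drug in floxed, drug in wild type, interaction). Scaling on probes above background left 1 list for the drug in wild type cells and median scaling 5 for the interaction; the cause was not tested. Cebpa between treated and untreated wild type cells changed from 0.23 to -0.080 without between-array normalization (adjusted p = 0.649), and passed in neither; the cause was not tested. With each array left out in turn, calls ranged over 8456 to 9236, 6933 to 7242, 3920 to 4563, 4041 to 4884, 2889 to 3739 and 2288 to 2893, and lists over 14 to 15, 13 to 14, 4 to 4, 4 to 4, 15 to 17 and 6 to 8. The shifts of basophil-higher and mast cell-higher genes ranged over -0.36 to -0.33 and 0.36 to 0.39 in treated floxed cells and -0.22 to -0.19 and 0.27 to 0.30 in the interaction, and kept direction and call under all other settings run. Of 61 list shifts that passed, single settings ended calls 34 times with an estimated correlation, 31 times over 3 scalings and 17 times with an array left out. Changes of probes near background are limited by signal, since 47.3% to 54.8% of probes lay above an intensity of 30. Quantile normalization was the setting already used, and the floor for low values was run as an offset of 50.

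With the replicate number as a block, 9367, 7525, 4414, 4858, 3410 and 2444 probes passed, and the same numbers of lists as without it. Same-numbered arrays did not deviate together: the correlation of their deviations from the group means was -0.173 to -0.0135 over 3 pairs of basophil and mast cell arrays and -0.376 to 0.156 over 18 pairs of cultured basophil arrays, 3 of them over 0.1. The samples thus share only a number.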

Other observations

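The comparison and the test in this part were chosen after the data were seen. Purified basophils, set against wild type basophils cultured without the drug in a fit of all 18 arrays with limma, differed at 9215 probes, 4641 higher and 4574 lower (n = 3 arrays a group), and at 8344 to 8516 with an array left out. Cebpa itself was -0.077 ± 0.11 log2 apart (adjusted p = 0.661), and Mcpt8, a basophil protease, read 39085 against 50584 in culture. Cell cycle genes were higher in the purified cells (24 higher and 0 lower of 24, median 2.32, adjusted p = 2.66e-06 with an estimated correlation), with the proliferation marker Mki67 at 5148 against 589. Neutrophil granule genes were higher (14 higher and 2 lower of 17, median 2.13, adjusted p = 3.25e-04 with an estimated correlation), with Camp at 14763 against 133 and Mpo at 32766 against 794. Eosinophil markers (6 higher and 0 lower of 7, median 2.51, adjusted p = 0.00141 with an estimated correlation), with Epx at 6182 against 122, and erythroid markers (7 higher and 0 lower of 8, median 1.65, adjusted p = 0.00129 with an estimated correlation) were higher beside them. Immediate early genes were higher too (13 higher and 0 lower of 16, median 1.83, adjusted p = 5.63e-05 with an estimated correlation), with Fos at 17942 against 1001.

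Cultured cells had more of the mast cell markers (1 higher and 12 lower of 18, median -1.68, adjusted p = 0.00516 with an estimated correlation in the purified cells), with Kit at 2225 against 280 and Cma1 at 8788 against 86.4. Granule proteases (1 higher and 9 lower of 14, median -1.14, adjusted p = 0.00901 with an estimated correlation), with Gzma at 3517 against 43.0, and megakaryocyte and platelet markers (0 higher and 7 lower of 8, median -0.91, adjusted p = 0.00390 with an estimated correlation) were also lower in the purified cells. The chemokines Ccl2 (6226 against 180.2) and Ccl7 (3404 against 24.1) were higher in culture. The lists named here kept their direction under the 3 other scalings, and the calls split into 6094 higher and 3369 lower without between-array normalization, 5342 and 3279 with median scaling and 4201 and 8110 with scaling on probes above background.

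Floxed alleles are often carried on a segment of another strain, a hypothesis for the genotype difference without the drug. Of the 100 tested genes nearest to Cebpa, 24.0% were called, against 25.6% of 12301 others (Fisher's exact test, two-sided, p = 0.818). A segment may also act on genes elsewhere, so it stays open.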
